A study of Drosophila melanogaster with 2 samples.

How the data were processed

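Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole embryos of Drosophila melanogaster aged 0 to 24 h, from a transgenic line that expresses the forkhead family transcription factor fd96Cb with a C-terminal green fluorescent protein (GFP) tag. The labels describe an anti-GFP immunoprecipitation, while their antibody field names fd96Cb itself. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The 2 samples are biological replicates numbered 2 and 3, and they form a single group, so replicate was set against replicate and the peaks were set against the genome, the annotation and weaker peaks.

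The authors deposited a peak list for each replicate, a list for the pooled replicates and an optimal set. That set came from the irreproducible discovery rate (IDR) procedure, which uses the agreement of peak ranks between replicates. Each peak carries a signal value and a −log10 q-value as the authors deposited them, together with its interval and summit, in dm6 coordinates per the labels. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The control library was not used here, and no read totals were in the files analysed, so the depth behind each list is unknown. The signal value served only to rank peaks within a list. Summits that lay outside their interval, at most 4 in a list, were moved to its edge.

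Genes and transcription start sites (TSSs) came from Ensembl release 115 (13945 protein-coding genes and 19607 TSSs on the arms X, 2L, 2R, 3L, 3R and 4) and sequence from Release 6 of the genome, whose chromosome lengths hold every peak. Coordinates below are 1-based in dm6. A summit within 1000 bp of a TSS was called a promoter summit, and the others were placed in 5′ UTR, coding exon, 3′ UTR, intron or intergenic sequence, in that order. IDR peaks were compared with the 23562 pooled peaks that overlap none of them. This rest ranks below the IDR peaks and may be largely background. These comparisons therefore set strong peaks against weak or no enrichment.

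Agreement of the replicates was the share of the 5743 strongest summits of replicate 2 within 100 bp of the 5743 strongest of replicate 3, against 1000 circular shifts along each arm. Location, arms and motifs were compared between IDR peaks and the rest with two-sided Fisher exact tests. Gene lists were compared with all other protein-coding genes in the same way, with Wilson 95% intervals. Motif shares within 50 bp of the summit were set against a flank of equal width centred 500 bp away, with the side drawn per peak, by exact two-sided McNemar tests. Signal ranks of peaks with and without a feature were compared by permutation tests with 100000 resamples. The number of summits within 20000 bp of fd96Cb was set against 10000 random positions on its arm. Benjamini-Hochberg adjustment was made over the 6 classes, the 28 gene lists, the 17 motifs or the 4 features tested together. All p-values and intervals cover counting over peaks or genes; these are not independent replicates, and the number of libraries is 2.

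The gene lists, the motifs, the tests and the rule for named genes were fixed before the data were examined. The rule names the gene with the nearest TSS to each of the 15 strongest IDR peaks, up to 4 members with the strongest promoter peak in each list that passes an adjusted p of 0.05, and fd96Cb and fd96Ca. List members were matched by exact symbol, and 24 of 645 list entries had no match among the protein-coding genes. Matching by synonym was added later, after the adjusted p-values had been seen, and is kept as an alternative. Alternatives chosen beforehand covered the number of peaks, the definition of a shared peak, the promoter window, the TSS set, the assignment to genes, matched backgrounds, window and flank sizes, the stronger part of the IDR peaks and each replicate alone. Comparisons with GC-matched genome positions, with patterns of the same letters, with genome windows grouped by GC and with shifted nearest-TSS assignments were added after the data were seen.

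The functions were tested on simulated data. All 200 planted gene lists were recovered (100%) among 14000 simulated genes. These lists were close to the ribosomal protein list in size and in share with a peak. Power for smaller lists or smaller differences was not simulated. A planted motif share of 9.57% gave an excess of 9.77 percentage points over 2497 simulated summits. Simulated summits and flanks had the same base composition, unlike those in the data. The motif test was therefore not simulated under a GC difference. The permutation test gave a p under 0.05 for 5.5% of 2000 features without a trend. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.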

Results

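ChIP-seq signal for GFP-tagged fd96Cb in 0 to 24 h embryos was recorded as peak lists from 2 biological replicates. The list of each replicate and the pooled list held 30000 peaks each, and the optimal IDR set held 5743. Whether a cap set this common length is not given, so the full lists may reach into background. All 5743 IDR peaks were the strongest 5743 of the pooled list, with a lowest signal value of 128.73 against 128.72 for the next pooled peak, so the set is a rank threshold on the pooled signal. IDR peaks had a median width of 364 bp and signal values up to 5351. The signal values are the authors' own, and sequencing depth is unknown.

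Most of the strongest peaks lay in promoters. CG14100 had the strongest peak (3L, 19590399 to 19590830, signal 5351), with its summit 95 bp upstream of the TSS, and Ugalt, which encodes a UDP-galactose transporter, the next (X, 2703661 to 2704116, signal 4936). These peaks ranked 1 and 2 in each replicate. px followed (2R, 22514091 to 22514517, signal 4239), then mRpL41, which encodes a mitochondrial ribosomal protein (2R, 15217529 to 15217990, signal 4183), with summits 202 and 129 bp upstream of a TSS, which for px is an internal TSS, so that this summit lies inside the gene. The other genes nearest to the 15 strongest peaks were cbt, Art3, the Polycomb group gene ph-p, CG11050, the chromatin protein gene Chro, Tcs5, PNPase, CG5611, CG4004, CG18549 and CG32772, with signal values from 4096 for cbt to 2988 for CG32772. Of these 15 peaks, 11 were in promoters (9 upstream of the nearest TSS, and those at Chro and PNPase downstream), 3 in introns (near cbt, CG11050 and CG32772) and 1 in intergenic sequence (near CG4004). Each stood within the first 16 peaks of replicate 2 and the first 19 of replicate 3.

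The replicates shared most of their strong peaks. Of the 5743 strongest summits of replicate 2, 4248 (74.0%) lay within 100 bp of one of the 5743 strongest of replicate 3, against a mean of 0.875% and a maximum of 1.24% in 1000 circular shifts (one-sided permutation p = 0.001 by shifts, the smallest they can give). Signal values of the 4248 matched peaks had a Spearman correlation of 0.804 and a Pearson correlation of 0.871 on the log scale, across peaks, which are not replicates. Of the IDR peaks, 83.7% lay within 100 bp of a strong summit of replicate 2 and 89.2% of replicate 3. The share was 74.5% for both replicates together and 1.71% for neither. The pooled list draws on both replicates, so these shares are partly built in. Agreement was 79.7% for the strongest 1000 peaks and 33.1% for the full lists.

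**Figure D1:**
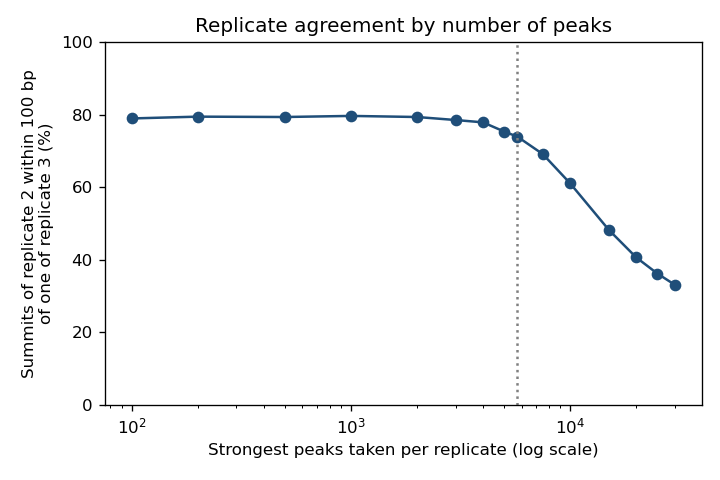
Share of the strongest summits of replicate 2 that lie within 100 bp of one of the same number of strongest summits of replicate 3, in percent, against the number of peaks taken from each replicate on a log scale. The share is 79.7% for 1000 peaks, 74.0% for 5743 (dotted line) and 33.1% for 30000.

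Promoters held 2511 of the 5743 IDR summits (43.7%, Wilson 95% interval 42.4 to 45.0), against 29.7% of the rest of the pooled list and 20.3% of the bases of the 6 arms (log2 odds ratio 0.88, Fisher exact adjusted p = 1.39e-88). Coding exons held 5 IDR summits (0.0871%), against 6.32% of the rest and 10.8% of bases (log2 odds ratio -6.14, Fisher exact adjusted p = 1.28e-134). The share was 0.209% with replicate 2 alone and 0.104% with replicate 3 alone. The 5 lay in exons of otp, Pde1c, klar, l(3)mbn and bif, genes named after their values were seen. The 3′ UTR share was 0.679% against 1.72% (Fisher exact adjusted p = 5.59e-10), and that of 5′ UTRs outside promoters 0.122% against 0.407% (adjusted p = 5.12e-04), a difference that did not pass with a promoter window of 5000 bp (adjusted p = 0.101) or against GC-matched genome positions (adjusted p = 0.480). Intergenic sequence held 19.9% against 24.6% (Fisher exact adjusted p = 5.52e-14). Introns held 35.5% against 37.3% (Fisher exact adjusted p = 0.0124), a difference that did not pass with replicate 2 alone (adjusted p = 0.0568) or against circular shifts (adjusted p = 0.408) and changed sign with a promoter window of 500 bp.

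**Figure D2:**
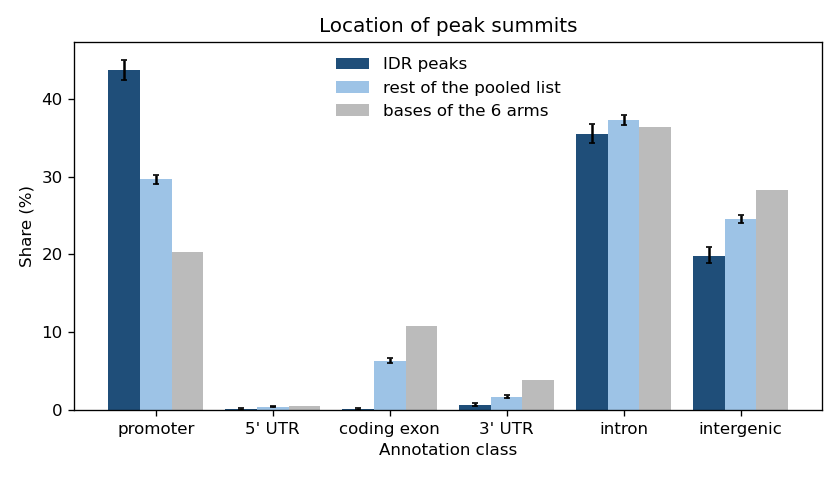
Share of summits in each annotation class, in percent, for the 5743 IDR peaks and the 23562 remaining pooled peaks (bars with Wilson 95% intervals), beside the share of bases of the 6 arms. Promoters hold 43.7% of IDR summits and coding exons 0.0871%.

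Among the 2511 promoter summits, 79.2% lay upstream of the nearest TSS, with a median position of -145 bp. The fullest 100 bp interval, from -200 to -100 bp, held 689 summits, and the one from 0 to 100 bp held 127. Promoter peaks were also the stronger ones. Promoters held 54.7% of the strongest of 5 equal bins of IDR peaks by signal and 38.0% of the weakest, and the mean signal rank of promoter peaks was 7.20 percentile points above that of other peaks (permutation adjusted p = 4e-05, two-sided). Peaks with and without the forkhead pattern RYAAAYA differed by 1.07 percentile points, which did not pass (permutation adjusted p = 0.238), nor did those with GTAAACA (1.84 points, adjusted p = 0.421) or GACGC (-3.32 points, adjusted p = 0.238). The promoter difference was 11.3 points by rank in replicate 2 and 4.29 by rank in replicate 3.

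**Figure D3:**
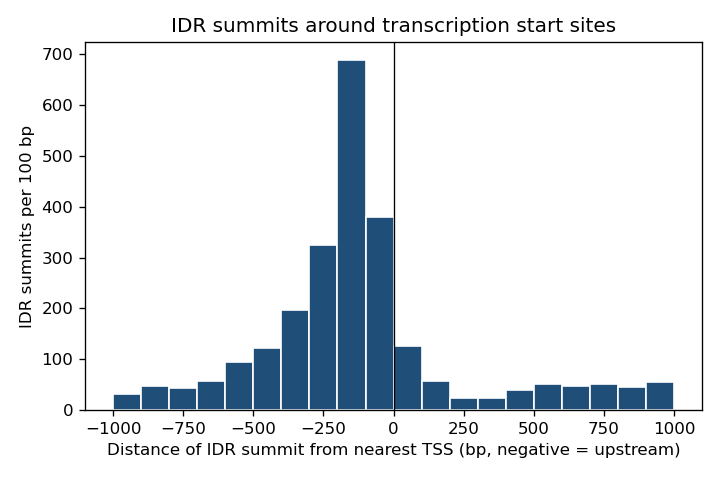
Number of IDR summits per 100 bp against the distance from the nearest protein-coding TSS in bp, with negative values upstream. The interval from -200 to -100 bp holds 689 summits and that from 0 to 100 bp holds 127.

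Ribosomal protein genes carried promoter peaks far more often than other genes, and chemoreceptor genes far less often. An IDR summit lay within 1000 bp of a TSS for 3052 of 13945 protein-coding genes (21.9%). Of the 86 ribosomal protein genes, 52 had one (60.5%, Wilson 95% interval 49.9 to 70.1, against 21.6% of other genes, Fisher exact adjusted p = 3.03e-13). The strongest were at RpS27 (3R, 25247370 to 25247719, signal 766.3), RpL34b (3R, 9401162 to 9401557, signal 736.6), RpL32 (3R, 30046109 to 30046478, signal 657.3) and RpL14 (3L, 8600820 to 8601095, signal 468.8). Of the 119 odorant and gustatory receptor genes, 2 had a promoter peak (1.68%, interval 0.462 to 5.92, Fisher exact adjusted p = 2.38e-09). These were Or88a (3R, 14108669 to 14108986, signal 585.7) and Gr32a (2L, 11113099 to 11113305, signal 371.1).

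The other 26 lists did not pass. The lowest adjusted p-values among them were for 7 of 12 glial genes and 8 of 15 genes of a chromatin list, which holds Polycomb and trithorax group genes beside insulator and pioneer factor genes (Fisher exact adjusted p = 0.0528 each), 9 of 19 cell cycle genes (adjusted p = 0.0682) and 9 of 21 Notch pathway genes (adjusted p = 0.144). Patterning lists gave 0 of 8 pair rule genes, 1 of 13 gap and maternal genes, 2 of 17 segment polarity and Wnt genes, 2 of 12 Hox cluster genes, 1 of 8 temporal series genes, 3 of 10 neural column genes and 5 of 15 Dpp pathway genes. Neural lists gave 1 of 16 neuroblast genes, 1 of 20 neuronal identity factors, 5 of 28 axon guidance genes and 2 of 17 mature neuron genes. Tissue lists gave 3 of 21 muscle regulators, 4 of 17 muscle structure genes, 3 of 16 tracheal genes, 3 of 15 gut genes, 2 of 12 epidermal genes and 4 of 12 germ line genes. The remaining lists gave 6 of 17 ecdysone genes, 6 of 17 heat shock genes, 8 of 31 proteasome genes, 0 of 11 testis-biased genes and 3 of 16 forkhead family genes, these being CHES-1-like, foxo and fkh, named after their values were seen. With replicate 3 alone the glial (Fisher exact adjusted p = 0.0431) and chromatin (adjusted p = 0.0132) lists passed, and assignment to the nearest TSS at any distance brought 15 lists past the threshold in place of 2.

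**Figure D4:**
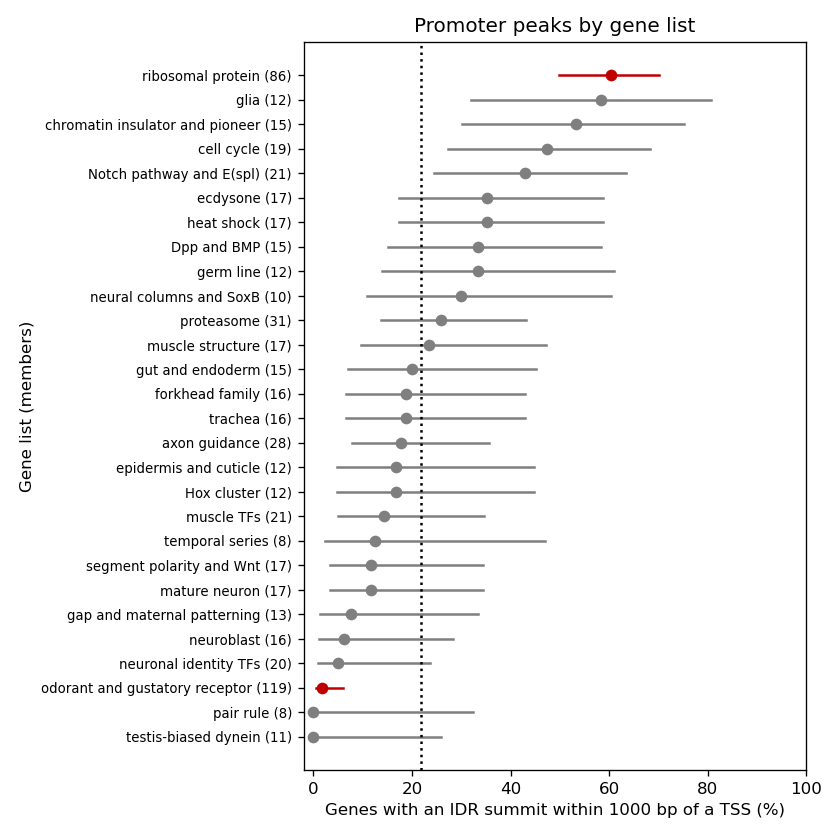
Share of genes with an IDR summit within 1000 bp of a TSS, in percent, for each of 28 gene lists with the number of matched members in brackets. Points are shares, lines are Wilson 95% intervals, red lists pass an adjusted p of 0.05, and the dotted line is the 21.9% of all protein-coding genes. The list named chromatin insulator and pioneer also holds Polycomb and trithorax group genes.

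Summits were AT-rich. Mean GC within 50 bp of IDR summits was 30.5% ± 7.71 (SD over 5743 peaks), against 43.6% ± 9.77 at the flank and 41.5% in the rest of the pooled list. GC was lower at the summit than at the flank for 84.2% of IDR peaks and for 51.0% of the rest. The strongest 5743 peaks of replicate 2 and of replicate 3 had 31.1% and 30.7%, and the genome as a whole 42.2%.

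**Figure D5:**
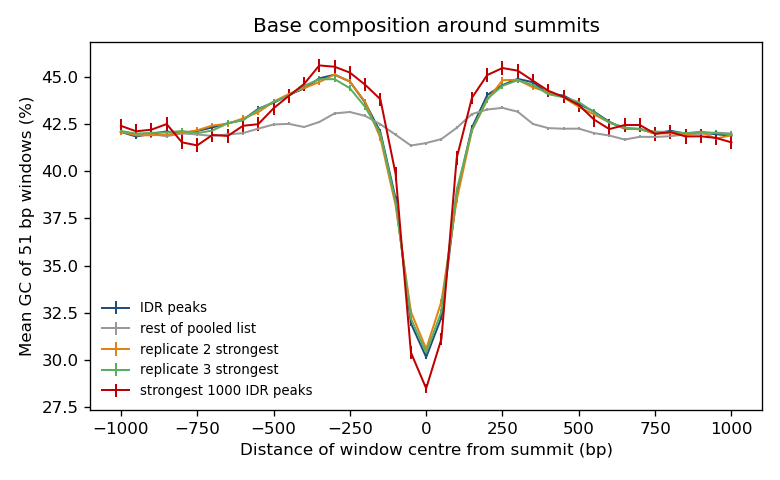
Mean GC of 51 bp windows, in percent, against the distance of the window centre from the summit in bp, for IDR peaks, the rest of the pooled list, the strongest 5743 peaks of each replicate and the strongest 1000 IDR peaks. Bars are standard errors over peaks. GC of IDR peaks is 30.2% at the summit and 45.1% at -300 bp.

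Of the 17 motifs, 5 were more frequent at the summit than at the flank, 7 less frequent and 5 did not pass. The degenerate forkhead pattern RYAAAYA occurred at 35.9% of IDR summits against 24.9% of flanks, a ratio of 1.44 (exact McNemar adjusted p = 1.85e-37). The strict forkhead motif GTAAACA occurred at 2.86% against 2.00% (exact McNemar adjusted p = 0.00551), a difference that did not pass with replicate 2 alone (adjusted p = 0.0953), in a window of 25 bp (0.131), with the flank at 300 bp (0.0934) or against GC-matched genome positions (Fisher exact adjusted p = 0.552). The replicates differed here, as replicate 3 alone gave 3.27% against 1.72% (exact McNemar adjusted p = 1.48e-07). The alternative forkhead motif GACGC fell from 10.6% at flanks to 2.72% at summits (exact McNemar adjusted p = 1.04e-65). The homeodomain motif TAATTA reached 12.5% against 5.08% (exact McNemar adjusted p = 1.17e-44), the GATA motif 18.9% against 11.4% (adjusted p = 2.16e-29) and the DREF motif 0.609% against 0.209% (adjusted p = 0.00185). The DREF difference did not pass with the flank at 300 bp (exact McNemar adjusted p = 0.0826), in the stronger part of the IDR peaks (0.545) or against GC-matched genome positions (Fisher exact adjusted p = 0.914), and changed sign outside promoters (0.417). Lower at summits were the GAGA motif (7.75% against 13.9%), the Pho motif (11.7% against 19.0%), CA repeats (0.575% against 4.04%) and the E-boxes CAGCTG, CAGGTG and CAKATG. CAKATG did not pass with replicate 3 alone (exact McNemar adjusted p = 0.246), with the flank at 300 bp (0.295) or 1000 bp (0.0927), in the stronger part of the IDR peaks (0.0538) or outside promoters (0.226), and changed sign against GC-matched genome positions. The Zelda, M1BP, Sox, POU and Ttk motifs did not pass against the flank.

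Against GC-matched genome positions, a comparison chosen after base composition had been seen, 14 of the 17 motifs did not pass. The differences for RYAAAYA (-1.06 percentage points, Fisher exact adjusted p = 0.446), TAATTA (-1.06 points, adjusted p = 0.233) and GAGA (1.08 points, adjusted p = 0.0863) changed sign. GATA (Fisher exact adjusted p = 0.446), GACGC (adjusted p = 0.0863), Pho (adjusted p = 0.446) and CAGGTG (adjusted p = 1) also did not pass. M1BP (15 peaks against 3, Fisher exact adjusted p = 0.0426) and CAGCTG (2.25% against 1.55%, adjusted p = 0.0426) were higher than at these positions, and CA repeats lower (0.575% against 1.04%, adjusted p = 0.0426). These positions were not matched on promoter class and fell in promoters in 19.9% of cases against 43.7% of IDR summits. Against the rest matched on both, M1BP (15 peaks against 11) and CAGCTG (2.32% against 2.17%) did not pass (Fisher exact adjusted p = 0.869 each), while CA repeats did.

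Against the rest of the pooled list, RYAAAYA was again more frequent in IDR peaks (35.9% against 26.7%, log2 odds ratio 0.62, Fisher exact adjusted p = 3.76e-41), as were the GATA (18.9% against 12.4%) and homeodomain (12.5% against 6.54%) motifs, while GTAAACA was not (2.86% against 2.58%, adjusted p = 0.359). Lower in IDR peaks were 7 motifs: GACGC (2.72% against 8.11%, Fisher exact adjusted p = 5.96e-55), Pho (11.7% against 19.2%), GAGA (7.75% against 11.0%), CA repeats (0.575% against 2.27%), CAGCTG (2.25% against 4.41%), CAGGTG (1.51% against 3.96%) and CAKATG (6.41% against 7.58%, adjusted p = 0.00359). With the rest matched on GC and promoter class, 5433 peaks of each kind remained. RYAAAYA was then less frequent in IDR peaks (34.9% against 37.6%, log2 odds ratio -0.17, Fisher exact adjusted p = 0.0323), CA repeats were less frequent (0.571% against 1.23%, adjusted p = 0.00567), and the other 15 motifs did not pass.

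No IDR summit lay within 20000 bp of fd96Cb (FBgn0004898, 3R, 25095012 to 25096099), where 38.7% of random positions on the arm also had none and the mean was 1.71. The nearest was 25180 bp away. Its neighbour and close relative fd96Ca (FBgn0004897, 3R, 25082684 to 25084878) lay 12852 bp from an IDR summit. The pooled list held 6 summits within the window, the strongest of rank 5818 (3R, 25088339 to 25088728, signal 126.9) in intergenic sequence between both genes and the weakest of rank 21109 (3R, 25095388 to 25095777) within fd96Cb. Replicate 2 listed 3 peaks there and replicate 3 listed 13, none among the strongest 5743 of either.

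By arm, IDR peaks numbered 47.2 per Mb on X (Poisson 95% interval 44.5 to 50.1), 45.3 on 2L, 46.1 on 3L, 40.9 on 3R and 37.3 on 2R. Chromosome 4, which is short and largely heterochromatic, had 17 peaks, or 12.6 per Mb (interval 7.35 to 20.2), with 8 of the strongest 5743 peaks in replicate 2 and 24 in replicate 3. The X held 19.4% of IDR peaks against 17.3% of the rest (log2 odds ratio 0.20, Fisher exact p = 2.30e-04).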

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

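Comparisons with GC-matched genome positions, with a gene-list background matched on the lowest GC near the TSS, with synonyms and with full lists for the correlation were chosen after the data were seen; the others, the rest matched on GC and promoter class among them, were planned. The promoter share kept its direction and passed in all 8 alternatives (log2 odds ratio 0.54 to 1.64), as did the X share in all 3 and the promoter strength difference in both. For location and arms, each replicate alone was still compared with the rest of the pooled list. That list draws on both replicates, so these alternatives are not independent of the replicate left out. Replicate agreement ranged from 33.1% for full lists to 79.7% for the strongest 1000 and stayed above its shifts. The Spearman correlation of matched peaks moved from 0.804 to 0.792 for the strongest 1000, 0.763 for IDR peaks and 0.826 for full lists. The summits within the window at fd96Cb went from 0 to 1 at 50000 bp.

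Lists past the threshold numbered 2 in the main test, 3 with a window of 500 bp or with 1 TSS per gene, 5 at 2000 bp, 4 at 5000 bp, 15 by nearest TSS, and 2 to 4 with a replicate left out. They numbered 2 with either matched background and 4 with synonyms. The chromatin list passed in 6 alternatives chosen beforehand: windows of 500 bp (Fisher exact adjusted p = 0.0237), 2000 bp (0.00293) and 5000 bp (0.0481), 1 TSS per gene (0.0356), nearest TSS (0.00184) and without replicate 2 (0.0132). It did not pass in the stronger part of the IDR peaks or without replicate 3 (0.132). The Notch list passed at 2000 bp (Fisher exact adjusted p = 0.0380) and 5000 bp (0.00577), the Dpp list at 2000 bp (0.0492) and the glial list without replicate 2 (0.0431), and all 3 by nearest TSS. With a window, a summit counts for every gene with a TSS inside it. Neighbouring genes of a list can thus share a summit, which the Fisher exact test does not allow for. Synonyms brought in the chromatin list (9 of 17, Fisher exact adjusted p = 0.0458) and the glial list (adjusted p = 0.0463); because that matching was chosen after both had been seen at 0.0528, and because neither passed against genes matched on TSS number and length (adjusted p = 0.373 each), they are not counted as passing. The ribosomal protein and receptor lists passed in all 11 alternatives.

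Motif results depended on base composition. Against GC-matched genome positions the difference for RYAAAYA changed from 11.0 to -1.06 percentage points and no longer passed (Fisher exact adjusted p = 0.446). The differences for TAATTA (-1.06), GAGA (1.08), CAGCTG (0.70) and CAKATG (0.42) also changed sign, and of these only CAGCTG passed (Fisher exact adjusted p = 0.0426). Against the rest matched on GC and promoter class, the log2 odds ratios of RYAAAYA (-0.17), GAGA (0.20), CAGCTG (0.10), CAGGTG (0.086) and Pho (0.0075) changed sign. DREF reversed outside promoters (-0.12 points), the intron share at a 500 bp window (log2 odds ratio 0.031) and the GTAAACA strength difference by rank in replicate 2 (-2.28 percentile points); the cause was not tested. Depth per library is unknown, so its effect on weaker peaks could not be measured.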

Other observations

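The tests of forkhead site recognition, library preference and gene territory, and those against positions or gene lists matched on GC, were chosen after the results they bear on had been seen. Some genes were the nearest gene to many IDR summits. CG43245 had 15 nearest summits, and Tlk, rdx, Ids and hth had 13 each. RapGAP1, CHES-1-like, shn, kirre, ush and CG13898 had 12 each, and px, Hr4, shep, hng3, Eip75B and pnt had 11 each. These genes were named after their values were seen. The counts were not set against the territory of each gene, which may account for them.

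Among all 2080 hexamers counted on both strands, the highest summit-to-flank ratios belonged to ATATTA (3.34, at 24.9% of summits against 7.44% of flanks), TATTAA (3.03) and AATATA (2.99), and the lowest to CCGGCG (0.0966) and CCCGGC (0.104). Median ratios fell from 2.41 for hexamers without G or C to 0.179 for those with 6. The forkhead core TAAACA had a ratio of 1.64, rank 149 of the 192 hexamers with 1 G or C.

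The full lists of the replicates differed on chromosome 4, with 42 peaks in replicate 2 and 404 in replicate 3. Peaks at the highest q-value made up 12.1% of the list of replicate 2 and 31.0% of that of replicate 3.

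The AT-rich summits were weighed against 3 explanations. Recognition of the forkhead site GTAAACA as their source is argued against by its summit-to-flank ratio, which ranked 112 among 210 patterns with the same letters, and RYAAAYA ranked 96 of 105. For position in noncoding classes, the GC difference between summit and flank was -12.2 percentage points for summits in introns and -12.98 for summits in intergenic sequence. The flanks, 500 bp away, were not held to the same class, so this comparison does not settle that explanation. A library preference for AT-rich fragments was set against genome windows of 400 bp in 10 equal groups by GC, but this test cannot decide it. The narrow GC dip at summits had already been seen. A window of 400 bp mixes the dip with its GC-richer flanks, so the test largely restates the dip. The group with the lowest GC held IDR summits 1.21 times as often as all windows, less than the 1.70 times of the windows between 35.25% and 37.5% GC. The ratio fell to 0.0793 in the group with the highest GC. A library preference, the control library, and recognition of another AT-rich sequence by fd96Cb or its partners stay open. The design holds no second group for a biological comparison.

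The location of summits was set against base composition. Genome positions matched to IDR summits on GC fell in coding exons 26.8 times as often as the summits did (2.33% against 0.0871%, or 0.209% with replicate 2 alone) and in promoters in 19.9% of cases against 43.7%. GC within 50 bp of the summit, taken alone, is therefore argued against for both the scarcity in coding exons and the promoter share. Base composition over longer stretches was not matched. The positions were drawn over the arms whether or not peaks can be called there. Open chromatin, which was not measured here, may contribute, and no test in these data separates it from binding by fd96Cb.

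The gene lists were set against base composition and gene territory. Random lists matched on the lowest GC near the TSS, TSS number and gene length reached the ribosomal protein count, and fell as low as the receptor count, in a share of 0.0001 each, the smallest that 10000 lists can give. By nearest TSS, 14 lists passed upward by Fisher exact test, and 2 of them exceeded circular shifts. IDR summits were nearest to 48 of 86 ribosomal protein genes against a shift mean of 11.6. They were nearest to 10 of 15 genes of the chromatin list (insulator, pioneer factor, Polycomb and trithorax group genes) against 3.72 (permutation adjusted p = 0.0140 each, from the smallest p the shifts can give). Both counts exceed what territory size gives to summits placed without regard to promoters. Shifts lowered the promoter share of summits from 43.7% to 20.2%, so they do not separate these lists from a general promoter preference. By promoter peaks, random lists matched on TSS number and gene length gave an adjusted p of 0.00280 for the ribosomal protein list and 0.373 for the chromatin list. For the other 12 the lowest adjusted p was 0.0746 (Notch, 12 of 21 against 5.46), and the Hox cluster gave 9 of 12 against 5.86 (permutation adjusted p = 0.252). For these 12 lists, territory size and distal binding cannot be told apart by this test. Most of them hold few members. Shifts also do not keep the avoidance of coding exons, a limit that applies to the 2 lists above as well.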
